A study of Triticum aestivum with 12 samples.

How the data were processed

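RNA from the leaf whorl of bread wheat was sequenced as 12 libraries in 4 groups of 3: the mite-resistant cultivar Byrd and the mite-susceptible cultivar Settler CL, each infested with wheat curl mites or not. Per the labels, each library pooled 3 plants, mites were placed 14 days after planting and tissue was taken 10 days after infestation. Groups were taken from the labels, and the columns of the table from its headers.

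The deposited table holds 1 FPKM value per gene and group (fragments scaled by transcript length and library size), which the authors made over the replicates of a group. Trimmomatic 0.39, TopHat2 and Cuffdiff 2.2.1 are named per the submitters' processing notes, with no roles stated. The genome build used for mapping and the settings of these tools are not given in the sources used here. Per the file headers, the gene identifiers are in 3 versions of the wheat annotation, and the newest version is printed here. The log2 fold changes of the deposited table give the first-named group over the second, and were checked against the ratio of its FPKM values: among genes above 0 in both groups, all but 2 differed from it by less than 0.01. Neither of the 2 was called in the 4 comparisons used, and their values were left as deposited. Its p-value columns, per the file headers, hold the authors' p-values with no adjusted value, and the smallest is 5e-05. The authors' calls were reproduced for every listed gene and all 6 deposited comparisons as an absolute log2 fold change of at least 1 with an unadjusted p under 0.05. The 4 comparisons that change 1 factor at a time were used, and the 2 that change cultivar and infestation together were not.

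The table lists 11016 genes, each called in at least 1 of the 6 comparisons. Genes called nowhere are not listed, so no background of all expressed genes was used, and every enrichment below is relative to the other listed genes. Values per library, total counts and standard errors were not used here: the depth of each library is unknown, no spread between replicates is printed, and the precision of a single value rests on the authors' p alone. Set tests with an estimated correlation could not be computed, since they need values per library. An adjustment of p over the listed genes alone was not used, since each of them had been chosen by a call. A gene with a p of exactly 1 was read as not tested. In the Byrd mite comparison such genes had a median FPKM of 0.304 in the higher group against 1.91 for the others, and 726 of 2414 had a fold change of at least the minimum. This reading is not stated in the table.

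The plan assumed adjusted p-values or counts per library. With neither at hand, the authors' calls at an unadjusted p were taken as the main result, which departs from the planned threshold of an adjusted p of 0.05 with no fold minimum. As an added, conservative alternative, p-values were adjusted by Benjamini-Hochberg over 155467 genes, the number in the RefSeq annotation of the IWGSC assembly, with unlisted genes counted at a p of 1. None of the table's identifiers matched that annotation (0 of 11016), so it served only for this number.

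Groups of genes were 28 keyword lists on the gene descriptions. Each list was tested among higher and among lower calls of each comparison with a two-sided Fisher's exact test against the other described and tested genes, with Benjamini-Hochberg adjustment over lists, comparisons and directions. The lists, their test with its adjusted threshold, and the rule for named genes were fixed before the data were examined; the threshold of the calls they take was not, and the rule ranks by the unadjusted p in place of the planned adjusted one. The keyword pattern for pathogenesis-related proteins also matched the word methionine, so a corrected list was added after the matched descriptions and first results had been seen, and its counts lead the text. Genes are not independent replicates, so these p-values describe the lists. Gene names in the text follow a rule. Per comparison, the rule takes the 6 largest rises and 6 largest falls among described calls with a finite fold change and at least 1 FPKM in the higher group. It adds the 2 members with the smallest p of each enriched list, ties going to the larger fold, and the 6 genes with the largest difference among those called in opposite directions in the cultivars. Some of the genes so taken are described only as part of their group.

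The difference between the cultivars' mite responses had no deposited test. It was tested after the table had been seen, with standard errors implied by each gene's fold change and p under a normal approximation, adjusted over the same 155467 genes. For 3437 genes with all 4 comparisons above the smallest p, the summed implied variances of the 2 mite comparisons and of the 2 cultivar comparisons, which come from the same libraries, had a median ratio of 0.977. A list's median difference was also set against 10000 random lists of the same size drawn from the listed genes, as a description.

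The tests were run on simulated data with known answers. For the difference between responses, the first pass mark was a recovery of 0.8 of genes simulated with a log2 difference of 2, and it was missed at 0.72. A test with the true errors recovered 0.775 on the same data, and above the smallest p both recovered 0.608, so the mark was too high for the simulated noise. It was replaced, after the miss, by equal recovery above the smallest p. The simulated p-values came from the same normal formula that the test inverts, so that equality was fixed in advance. These simulations therefore do not show whether the normal approximation holds for the authors' p-values. Unchanged genes passed an unadjusted p of 0.05 at a share of 0.0451. The list test called the jasmonate list in 0.015 of draws of random calls in the Byrd mite comparison, and in 0.985 of draws with its members taken 3 times as often.

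Alternatives were a mean of at least 1 FPKM over groups, p at most 0.01, an absolute log2 fold change of at least 2, the conservative adjustment, leaving out chromosome 3D, leaving out the 3828 gene models with the suffix LC (low confidence), and centring fold changes on the median of uncalled genes. All but the FPKM minimum were chosen after the table had been seen. Centring left the deposited p-values unchanged. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.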

Results

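Wheat curl mites are microscopic mites that feed in the rolled leaves of the whorl, where new leaves emerge. Transcript levels in the whorl were measured in the mite-resistant cultivar Byrd and the mite-susceptible cultivar Settler CL, infested or not, in 3 libraries per group. The comparisons ask how each cultivar responded to 10 days of mite feeding and how the cultivars differed with and without mites. The authors' deposited table gives 1 FPKM value per gene and group for 11016 genes. No replicate values were used here, so no spread stands beside any level, and whether a difference exceeds the replicate spread is given by the authors' unadjusted p. The table does not say whether the replicates were separate pots or plantings, so these p-values measure the spread between the libraries used. Median levels of the listed genes in the authors' deposited table were 1.05 FPKM in non-infested Byrd, 1.20 in infested Byrd, 1.31 in non-infested Settler CL and 1.16 in infested Settler CL.

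**Figure D1:**
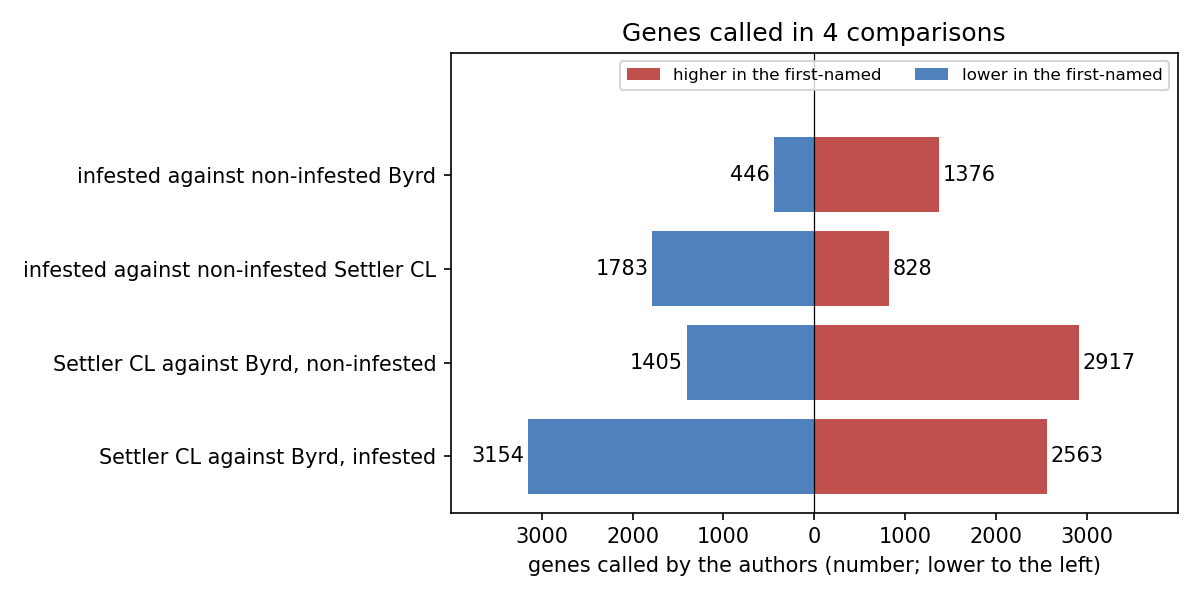
Horizontal bars give the number of genes called higher (right) and lower (left) in the first-named group of each of 4 comparisons, by the authors' calls. The mite response of Byrd held 1376 rises and 446 falls, that of Settler CL 828 rises and 1783 falls.

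In infested Byrd, genes of jasmonate synthesis and signalling, WRKY transcription factors, protease inhibitors and other defence groups rose. Of 55 tested genes of the jasmonate list, a hormone of wound and herbivore defence, 32 rose and 1 fell. Lipoxygenases oxidise fatty acids, and some act in the first step of jasmonate synthesis. The descriptions do not say which of the listed lipoxygenases do, and they entered the list by keyword. Lipoxygenases showed some of the largest rises. In the authors' deposited table, TraesCS6D03G0269200 went from 0.267 to 30.3 FPKM (log2 6.83, p = 5e-05) and its neighbour TraesCS6D03G0269100 from 0.143 to 17.1 FPKM (log2 6.90). In total 1376 genes rose and 446 fell, so that rises made up 75.5% of the calls.

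The 32 jasmonate rises compared with 8.86 expected from the other listed genes (adjusted exact p = 2.54e-10, Fisher's exact test). They included 13 lipoxygenases, 10 JAZ or TIFY repressors of jasmonate signalling, 5 allene oxide synthases and 3 oxophytodienoate reductases, the latter enzymes of jasmonate synthesis. WRKY factors, regulators of defence genes, rose in 31 of 53 tested members (adjusted exact p = 2.54e-10). Among them were TraesCS1D03G0718500 (log2 5.27), TraesCS5B03G0589800 (log2 3.39) and TraesCS5B03G0490500 (log2 2.57) in the authors' deposited table. Protease inhibitors, which hinder the digestion of plant protein by feeding animals, rose in 30 of 58 tested members (adjusted exact p = 1.25e-08). Of these, 9 were chymotrypsin inhibitors, 8 trypsin inhibitors and 6 wound-induced inhibitors. The list also held 13 genes whose description names lipid transfer, of which 3 rose. The chymotrypsin inhibitor TraesCS1B03G0069700 went from 2.05 to 17.3 FPKM and TraesCS1D03G0051100 from 6.0 to 46.8 FPKM in the authors' deposited table, both at p = 5e-05.

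Phenylpropanoid genes, which lead to lignin and phenolic compounds, rose in 33 of 105 tested members (adjusted exact p = 0.00101), while 12 fell (adjusted exact p = 0.053). Without chromosome 3D the falls were enriched too (12 of 95, adjusted exact p = 0.0247). The rises included 10 phenylalanine ammonia-lyases, the entry enzyme of the pathway, and 10 dirigent proteins, which steer the coupling of lignin-related phenolics. Dirigent genes had the largest finite rises among called genes with a description and at least 1 FPKM: in the authors' deposited table TraesCS4A03G1071100 went from 0.0452 to 18.9 FPKM (log2 8.71, p = 0.0026) and TraesCS7D03G0120300 from 0.0762 to 15.8 FPKM (log2 7.70, p = 0.00335). A further member, TraesCS4D03G0245600, reached log2 5.52 in the authors' deposited table at p = 0.021. The phenylalanine ammonia-lyase TraesCS4A03G0998200 (log2 3.93) and the dirigent gene TraesCSU03G0342500 (log2 3.82) had p = 5e-05 in the authors' deposited table.

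Pathogenesis-related proteins rose in 32 of 86 tested members of the corrected list (adjusted exact p = 4.01e-05). They included a beta-1,3-glucanase, TraesCS3B03G1306500, from 0.581 to 7.17 FPKM, and a chitinase, TraesCS2A03G0857500, from 0.554 to 6.80 FPKM in the authors' deposited table. These enzymes break down cell wall polymers of fungi, and chitinase also breaks down the chitin of arthropods. Glutathione S-transferases, which detoxify reactive compounds, rose in 17 of 46 tested members and none fell (adjusted exact p = 0.00711). The glutathione S-transferase TraesCS7D03G1105100 rose by log2 2.57 and TraesCS2B03G0589200 by log2 2.16 in the authors' deposited table. Ethylene genes rose in 12 of 28 (adjusted exact p = 0.00664), with the ACC synthase TraesCS2D03G0897400 at log2 1.99 and the ACC oxidase TraesCS1A03G0217500 at log2 1.37 in the authors' deposited table, both enzymes of ethylene synthesis. Cytochrome P450 genes rose in 33 of 126 (adjusted exact p = 0.0199), with the neighbours TraesCS5A03G0009400 (log2 3.68) and TraesCS5A03G0009300 (log2 3.18) in the authors' deposited table.

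Cell wall growth genes rose in 32 of 124 tested members (adjusted exact p = 0.0356). Examples in the authors' deposited table were the cellulose synthase-like gene TraesCS2D03G0455400 (log2 1.82) and the xyloglucan endotransglucosylase TraesCS7D03G0992500 (log2 1.75). Nitrogen genes rose in 19 of 66 (adjusted exact p = 0.0496), among them the asparagine synthetases TraesCS4D03G0481800 (log2 4.88) and TraesCS4A03G0227300 (log2 2.78) of the authors' deposited table, which make a nitrogen transport compound. Intracellular immune receptors of the NLR class were rarer among the rises than other listed genes, with 11 of 236 against 38.01 expected (adjusted exact p = 2.15e-06). The same held for mobile element genes, with 12 rises of 239 (adjusted exact p = 3.99e-06), and 25 of these fell (adjusted exact p = 0.0073). Between the non-infested cultivars NLR genes had 75 higher and 70 lower calls, and mobile element genes 91 and 74. Genes listed through such calls lower these shares of rises. After centring on uncalled genes, ethylene genes (8 rises, adjusted exact p = 0.159) and cell wall growth genes (26 rises, adjusted exact p = 0.0996) were no longer enriched among the rises. With a mean of at least 1 FPKM, neither were phenylpropanoid (adjusted exact p = 0.187), cytochrome P450 (adjusted exact p = 0.166) or nitrogen genes (adjusted exact p = 0.324).

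Falls in Byrd were fewer. The largest finite falls among called genes with a description and at least 1 FPKM in the authors' deposited table were a proline-rich protein, TraesCS4B03G0948800 (log2 -4.08, p = 0.041), and a protein kinase, TraesCSU03G0408100LC (log2 -3.53, p = 5e-05). The cold-responsive gene TraesCS2D03G0959600 (WCOR15) fell from 3.67 to 0.552 FPKM at p = 5e-05 in the authors' deposited table, while infested Settler CL stood at 12.7 FPKM. A germin family gene, TraesCS3D03G0119500, had log2 -2.39 (p = 0.0036) in the authors' deposited table. With the conservative adjustment 579 rises and 89 falls remained in Byrd, since the deposited calls rest on unadjusted p-values.

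In infested Settler CL falls outnumbered rises, and the jasmonate list went down. Of 42 tested jasmonate genes 28 fell and none rose (adjusted exact p = 2.56e-09 for the falls, Fisher's exact test). WRKY factors also rose as a list, in 19 of 40 tested members (adjusted exact p = 1.25e-08). The single genes were mostly not the same, since 6 WRKY factors rose in both cultivars and 3 rose in Byrd and fell in Settler CL. Photosynthesis genes fell in 32 of 84. The totals were 828 rises and 1783 falls, with rises at 31.7% of the calls.

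Among the jasmonate falls were 13 lipoxygenases, 10 JAZ or TIFY genes and 2 allene oxide synthases. In the authors' deposited table the lipoxygenase TraesCS6A03G0314500 dropped from 16.1 to 0.815 FPKM (log2 -4.30) and TraesCS6B03G0405500 from 3.04 to 0.110 FPKM (log2 -4.79), both at p = 5e-05. The WRKY rises were led by TraesCS2A03G0334500 (log2 3.31) and TraesCS2B03G0452500 (log2 2.69) in the authors' deposited table. Pathogenesis-related proteins rose in 20 of 90 tested members of the corrected list (adjusted exact p = 0.00167) and fell in 8. A beta-1,3-glucanase, TraesCS3A03G1130300, rose from 0.391 to 1.91 FPKM, and a chitinase, TraesCS2D03G0798500, from 0.415 to 1.80 FPKM, in the authors' deposited table at p = 5e-05. Glutathione S-transferases rose in 11 of 48 (adjusted exact p = 0.0214). At the smallest p the members with the largest folds in the authors' deposited table were TraesCS1A03G0502600 (log2 3.15) and TraesCSU03G0111800 (log2 2.12).

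Receptor kinases, which sense signals at the cell surface, rose in 34 of 182 tested members (adjusted exact p = 0.000959) and 33 listed members fell. TraesCS5D03G1162000 went from 0.869 to 4.23 FPKM and TraesCS3A03G0036900 from 0.154 to 1.53 FPKM in the authors' deposited table. Glycosyltransferases rose in 17 of 95 (adjusted exact p = 0.0367) and 18 listed members fell, while after centring 21 rose and 10 fell. The rises included TraesCS2D03G0056500 at log2 3.48 and TraesCS5D03G1096100 at log2 2.23 in the authors' deposited table. Calcium-related genes rose in 11 of 50 (adjusted exact p = 0.029) and 13 listed members fell, among the rises the calcium-binding proteins TraesCS5A03G0584300 (log2 3.53) and TraesCS5D03G0552900 (log2 2.50) of the authors' deposited table. Ribosomal protein genes rose in 32 of 149 (adjusted exact p = 8.77e-05), and 21 listed members fell. The plastid-type ribosomal gene TraesCS4A03G0395900 went from 3.27 to 21.1 FPKM in the authors' deposited table.

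Photosynthesis falls (adjusted exact p = 0.00105) included 5 genes of the Rubisco small subunit and 12 annotated as its large subunit; Rubisco fixes carbon dioxide. The small subunit gene TraesCS2A03G0131800 dropped from 313.5 to 92.5 FPKM (log2 -1.76, p = 5e-05) in the authors' deposited table. Among models without the suffix LC 11 falls stood (adjusted exact p = 0.412), and after centring 19 (adjusted exact p = 0.099). NLR genes fell in 64 of 238 tested members (adjusted exact p = 0.0425), among those at the smallest p TraesCS5D03G1161800 (log2 -3.03) and TraesCS2D03G1341400 (log2 -2.48) in the authors' deposited table. After centring 40 NLR falls stood (adjusted exact p = 0.309), so that neither list was then enriched among the falls. Cell wall growth genes were rare among the rises, at 3 of 140 (adjusted exact p = 0.0114), or 5 after centring. This list had 68 higher and 13 lower calls between the non-infested cultivars, and genes listed through such calls lower that share. With a mean of at least 1 FPKM, pathogenesis-related proteins of the corrected list, receptor kinases, glycosyltransferases and glutathione S-transferases were no longer enriched among the rises, nor NLR genes among the falls.

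The largest finite rise of a called gene with a description and at least 1 FPKM in the authors' deposited table was a methyltransferase domain gene, TraesCS4B03G0828000, from 0.204 to 13.2 FPKM (log2 6.01, p = 5e-05). It was followed in the authors' deposited table by an aspartic proteinase, TraesCS7D03G1125300 (log2 5.21), and an S-acyltransferase, TraesCS2D03G0107600 (log2 5.19, p = 0.044). A cytochrome P450 gene, TraesCS2D03G0047400, had the largest such finite fall (log2 -7.79, p = 0.046 in the authors' deposited table). In that table it had 11.1 FPKM in non-infested Settler CL and at most 0.05 in every other group, both Byrd groups included. The S-acyltransferase had 0.119 FPKM in non-infested Settler CL, against 4.36 in infested Settler CL, 9.69 in non-infested Byrd and 11.2 in infested Byrd. For these genes the non-infested Settler CL group is the one that stands apart. Of the 6 largest falls so chosen, 4 lay on chromosome 6B, among them the receptor kinase TraesCS6B03G0132300, which went from 1.63 to 0.0431 FPKM, and the RNA polymerase subunit TraesCS6B03G1029000, from 6.21 to 0.177 FPKM in the authors' deposited table. Both genes, and the methyltransferase domain gene above, belong to a set near absent or near exclusive in infested Settler CL, described under other observations. For that set a difference between the infested and non-infested plants is a candidate explanation. These values do not separate it from a response to mites. Such a difference was not tested for most other calls between infested and non-infested Settler CL, where it would coincide with infestation too.

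Of the 1783 falls, 397 lay on chromosome 3D, against 145 expected (adjusted exact p = 1.08e-102, Fisher's exact test). From gene number 852800 to the last listed gene of the chromosome, 343 of 516 listed genes fell and 6 rose, with a median log2 fold change of -1.25 (SD over 463 tested genes 0.767). In Byrd 2 of these genes fell and 20 rose, with a median of 0.08. At the other end of 3D, 16 of the 23 listed genes up to number 26500 rose in Settler CL. Both boundaries were placed after the clustering had been seen.

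**Figure D2:**
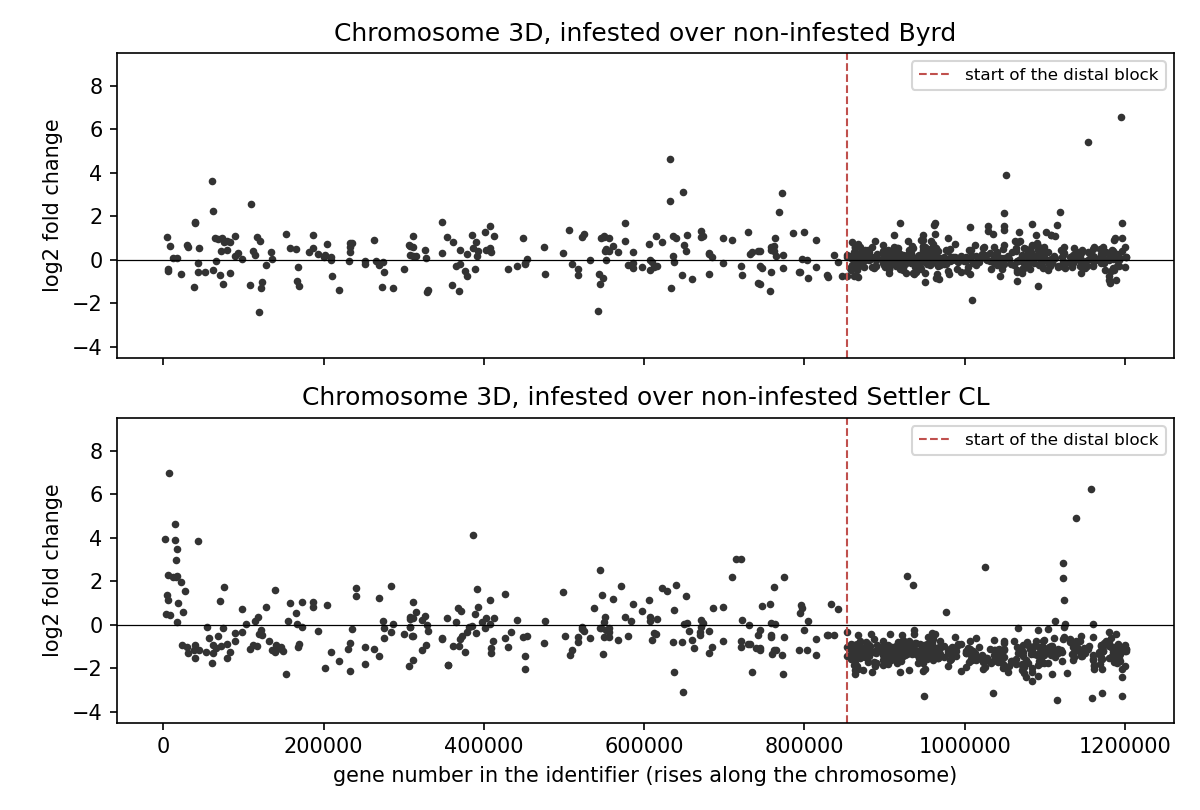
Each point is a tested listed gene of chromosome 3D, placed by the gene number in its identifier (x) and its log2 fold change of infested over non-infested plants (y), for Byrd (top) and Settler CL (bottom). Right of the dashed line, at gene number 852800, the median is 0.08 in Byrd and -1.25 in Settler CL.

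Without chromosome 3D there were 1386 falls and 784 rises. Uncalled genes had a median log2 fold change of -0.19 in Settler CL, 0.09 in Byrd, 0.17 between non-infested and 0.13 between infested cultivars, and centring on them moved the Settler CL split from 31.7% to 45.4% rises.

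Some genes rose with mites in both cultivars, and others moved in opposite directions. Of the genes tested in both, 171 rose in both, against 83.3 expected from the other listed genes (odds ratio 2.83, Fisher's exact p = 5.02e-23). Falls were shared by 40 genes against 70.3 expected (p = 1.12e-05, Fisher's exact test). A group of 134 genes rose in Byrd and fell in Settler CL, and 4 did the reverse, which was fewer than the 218.8 and 26.8 expected from the listed genes (Fisher's exact p = 1.96e-13 and 3.42e-08). Of the jasmonate list 13 genes rose in Byrd and fell in Settler CL, and none rose in both. Every listed gene was called somewhere, so these expected counts hold for the table. With the same calls, those among the 6610 genes tested in both, set over the 155467 genes of the annotation, they would be 3.54, 2.99, 9.30 and 1.14 genes in the same order. Taking every call of each cultivar would give higher values than these. For shared falls and opposite calls the direction of the comparison depends on whether the listed or the annotated genes are taken.

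**Figure D3:**
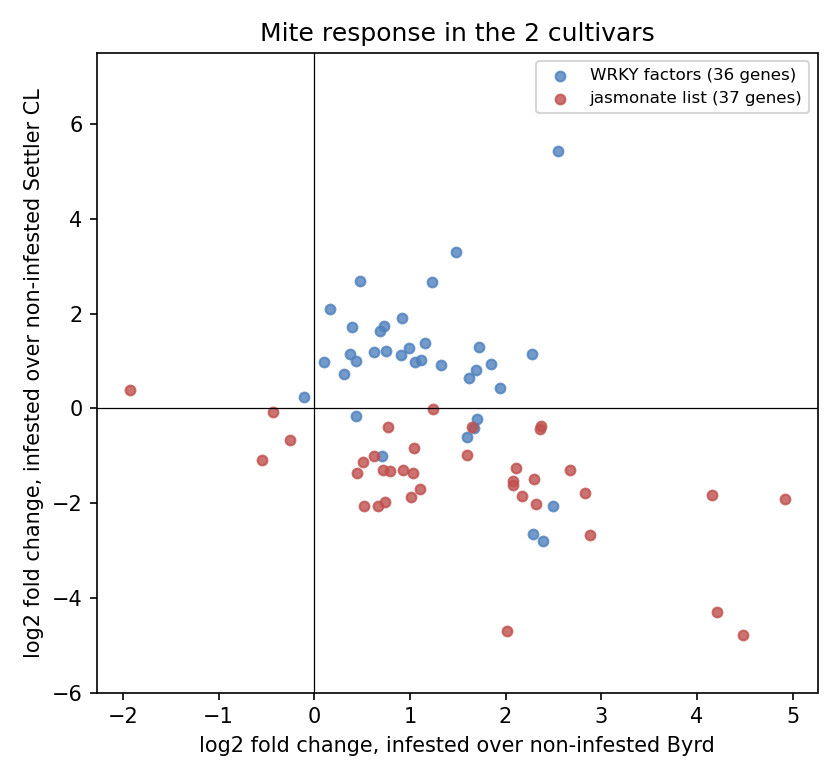
Each point is a gene of the jasmonate list (37 genes) or a WRKY factor (36 genes) tested in both cultivars; x is the log2 fold change of infested over non-infested Byrd and y that of Settler CL, both from the authors' values. Jasmonate genes lie mostly to the lower right, with a median difference of -2.72 (Settler CL minus Byrd), and WRKY factors mostly to the upper right, with 0.22.

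The difference between the 2 responses passed an adjusted p of 0.05 for 652 of 6529 genes under the approximate test. In 598 of these the response of Settler CL lay below that of Byrd, and in 54 above. The fold changes in this test were not centred and chromosome 3D was kept. Uncalled genes had medians of -0.19 in Settler CL and 0.09 in Byrd, so the split includes that shift and the 3D block. The jasmonate list held 27 of the 598. Its median difference (Settler CL minus Byrd) was -2.72, and no random list of the same size lay as far out (permutation of list members, p = 1e-04, the smallest that 10000 random lists can give; adjusted p = 0.00135). The cell wall growth list had a median difference of -1.10 (permutation p = 1e-04, adjusted p = 0.00135) and protease inhibitors -1.04 (adjusted permutation p = 0.0422). WRKY factors had 0.22 (adjusted permutation p = 0.0036) and heat shock genes 0.08 (adjusted permutation p = 0.00405), both above the other listed genes, yet the 7 WRKY factors that passed the test all had the lower response in Settler CL. The other lists that stood apart from the listed genes were phenylpropanoid genes at -0.93 (adjusted permutation p = 0.0422), sugar transport and storage at 0.04 (adjusted permutation p = 0.00594) and chlorophyll breakdown and senescence at 0.11 (adjusted permutation p = 0.026). The permutation p measures the distance of a list from the median of the listed genes, not from 0. A list median near 0 marks similar median responses in the 2 cultivars. At an adjusted p of 0.01 the test gave 362 genes.

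Without mites, cell wall, photosynthesis and peroxidase genes were frequent among the genes higher in Settler CL than in Byrd, and NLR and mobile element genes were frequent among the lower ones. Cell wall growth genes were higher in 68 of 143 tested members (adjusted exact p = 0.000324) and NLR genes lower in 70 of 294 (adjusted exact p = 0.000264), while 75 NLR genes were higher. After centring on uncalled genes, cell wall growth (adjusted exact p = 0.088), photosynthesis (adjusted exact p = 0.147) and peroxidase genes (22 higher, adjusted exact p = 0.37) were no longer enriched, and with a mean of at least 1 FPKM neither were the lower NLR genes (adjusted exact p = 0.314). In all, 2917 genes were higher and 1405 lower in Settler CL, and 506 of the higher genes were listed at 0 in Byrd.

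The cellulose synthase-like gene TraesCS3B03G0211100 stood at 3.71 FPKM in Settler CL against 0.130 in Byrd, and the xyloglucan endotransglucosylase TraesCS7A03G0359900LC at 11.7 against 0.573 FPKM, in the authors' deposited table. Peroxidases, which act on cell walls and reactive oxygen, were higher in 35 of 68 tested members (adjusted exact p = 0.00337). TraesCS6B03G0148100 (log2 3.36) and TraesCS7B03G0945200 (log2 3.28) were in this group in the authors' deposited table. Photosynthesis genes were higher in 39 of 82 (adjusted exact p = 0.0112). The chlorophyll a-b binding gene TraesCS1A03G0896500LC, of the light-harvesting antenna, had 652 FPKM against 54.9 in the authors' deposited table. The photosystem protein gene TraesCS6B03G1261000 had 39.3 against 3.33 FPKM in the authors' deposited table. Pathogenesis-related proteins of the corrected list were higher in 34 of 71 (adjusted exact p = 0.0162), with the thaumatin-like gene TraesCS5B03G0034800 at log2 4.33 and the glucanase TraesCS6B03G0150700 at log2 2.66 in the authors' deposited table. WRKY factors were rarely higher, at 2 of 31 (adjusted exact p = 0.0166). That share depends on what is listed, since WRKY factors had 31 rises with mites in Byrd and 19 in Settler CL. Genes listed through such calls lower it.

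NLR genes lower in Settler CL included TraesCS1B03G0303100, at 0.715 against 19.9 FPKM, and TraesCS2B03G0087300, at 0.341 against 5.79 FPKM in the authors' deposited table. Mobile element genes were lower in 74 of 310 (adjusted exact p = 0.000149) and higher in 91, the lower ones including in the authors' deposited table TraesCS3B03G0876500LC (log2 -2.15) and TraesCS7B03G1190500LC (log2 -2.03). The largest finite differences of called genes were of a near presence and absence kind. A ribose-5-phosphate isomerase gene, TraesCS7B03G0602100LC, had 34.2 FPKM in Settler CL and 0.0624 in Byrd, and the tumor-protein homolog TraesCS6B03G0004500 136 against 0.281 FPKM in the authors' deposited table. In the other direction the oxygenase TraesCS2B03G0170900 had 0.0546 against 18.6 FPKM and the serine synthesis gene TraesCS1B03G0671200 0.0869 against 28.5 FPKM in the authors' deposited table. The drought-responsive gene TraesCS1D03G0082000 (RD22) had log2 -8.12 and the auxin conjugation gene TraesCS6B03G1254600 log2 -7.68 in the authors' deposited table. A gene copy whose sequence differs from the reference in 1 cultivar can also be counted low there, which these values do not separate from a lower level.

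With mites, the cultivars differed in jasmonate and phenylpropanoid genes, which were lower in Settler CL, and in heat shock and ribosomal genes, which were more often higher than lower. Jasmonate genes were lower in 44 of 58 tested members (adjusted exact p = 6.28e-10) and higher in 3. Phenylpropanoid genes were lower in 63 of 118 (adjusted exact p = 4.5e-05) and higher in 16. In total 2563 genes were higher and 3154 lower in infested Settler CL, of which 454 of the lower lay on chromosome 3D.

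The lipoxygenase TraesCS6A03G0314500 had 84.8 FPKM in infested Byrd and 0.815 in infested Settler CL, and TraesCS6B03G0405500 18.9 against 0.110 FPKM, in the authors' deposited table. Of 21 listed lipoxygenases 19 were lower in infested Settler CL, as were 13 of 19 phenylalanine ammonia-lyases, 22 of 38 dirigent genes and 15 of 27 expansins, proteins that loosen cell walls. Dirigent genes TraesCS4A03G1071100 (log2 -7.77) and TraesCS7D03G0120300 (log2 -6.72) had p = 5e-05 in the authors' deposited table. The largest finite difference among called genes with a description was a patatin, a lipid-cleaving enzyme: TraesCS7A03G0027000 had 77.7 FPKM in infested Byrd against 0.185 (log2 -8.72, p = 5e-05), after 4.49 FPKM in non-infested Byrd, in the authors' deposited table. NLR genes were lower in 115 of 280 (adjusted exact p = 0.011) and higher in 80, but the lower calls were not enriched with a mean of at least 1 FPKM (adjusted exact p = 0.324) or under the conservative adjustment (adjusted exact p = 0.205). The lower calls included TraesCS5B03G1037400 (log2 -5.79) and TraesCS2B03G1524200 (log2 -5.69) of the authors' deposited table. Without mites both also stood lower, at 0.643 against 3.72 and 0.00538 against 4.06 FPKM, though only the first was called.

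Heat shock and chaperone genes were higher in 32 of 71 tested members (adjusted exact p = 0.00557). The heat shock protein gene TraesCS5D03G1081100 had 114 FPKM against 15.1, and the chaperone TraesCS7B03G0362000 13.6 against 1.30 FPKM in the authors' deposited table. Without mites they already had 80.5 against 17.8 and 6.91 against 1.75 FPKM. Sugar transport and storage genes were higher in 28 of 69 (adjusted exact p = 0.0431), a result that did not hold without chromosome 3D (28 of 68, adjusted exact p = 0.0562) or after centring (20 of 69, adjusted exact p = 0.407). The SWEET sugar transporter TraesCS6B03G0033500 stood at 11.7 against 0.323 FPKM and the sucrose synthase TraesCS3B03G0505900 at 3.39 against 0.498 FPKM in the authors' deposited table. Both were already higher in Settler CL without mites, at 9.95 against 0.574 and 2.99 against 0.541 FPKM. Ribosomal protein genes were higher in 60 of 154 (adjusted exact p = 0.00416), and pathogenesis-related proteins of the corrected list in 41 of 100 (adjusted exact p = 0.00958). With an absolute log2 fold change of at least 2, heat shock (adjusted exact p = 0.558), ribosomal (adjusted exact p = 0.152) and pathogenesis-related genes (adjusted exact p = 0.259) were no longer enriched, and among models without the suffix LC the ribosomal genes were not (adjusted exact p = 0.0684). A cysteine protease, TraesCS5D03G0507800, had 167 FPKM against 0.656 in infested and 177 against 0.768 in non-infested plants in the authors' deposited table. Across the 2 cultivar comparisons 1167 genes were higher and 896 lower in Settler CL both with and without mites, against 634 and 399 expected from the listed genes (Fisher's exact p = 5.12e-178 and 1.52e-220).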

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

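The test of the difference between the cultivars' responses was chosen after the table had been seen, as was the choice of explanations weighed for the jasmonate genes; the bounds on their tests were set before the values were computed, except in the test of a raised level, whose genes were chosen anew and whose rule was made stricter after its values had been seen. The genes and the list below are given because their responses to mites differed between Byrd and Settler CL.

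Each of 6 named genes rose in Byrd and fell in Settler CL, with log2 fold changes from the authors' deposited table. The differences (Settler CL minus Byrd, log2) were -10.60 for the dirigent gene TraesCS7D03G0120300 and -9.27 for the lipoxygenase TraesCS6B03G0405500. They were -8.79 for TraesCS5D03G1228900, a tubulin-binding cofactor domain gene, and -8.51 for the lipoxygenase TraesCS6A03G0314500. The acid phosphatase TraesCS4B03G0940000 had -7.17 and the nuclease TraesCS2D03G1133700 -6.79. All 6 passed an adjusted p of 0.05 in the approximate test. Genes called in opposite directions numbered 138, and 126 of them passed the adjusted threshold of the approximate test. Selecting opposite calls fixes most of that outcome.

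Jasmonate genes differed as a list, with a median of -2.72 (Settler CL minus Byrd). The block on chromosome 3D does not account for the falls in Settler CL, since 96.4% of them lay on other chromosomes. A shift in scaling of the size seen in uncalled genes (log2 -0.19 in Settler CL, 0.09 in Byrd) does not account for most of the calls. After centring 89.3% of them stood in the cultivar that lost more. Centring kept the deposited p-values, so it could end only calls near the fold minimum. The median log2 fold change was -1.66 for the falls in Settler CL and 2.11 for the rises in Byrd. A raised level in non-infested Settler CL alone would put infested plants back at the level of non-infested Byrd. The median log2 ratio to that level was -1.02 in the genes that fell, which are picked for low values in infested Settler CL. It was -0.74 in 31 genes that rose in Byrd (95% interval -1.35 to -0.21), where non-infested Settler CL lay 0.54 above Byrd. Genes that rose in Byrd are picked partly for low values in non-infested Byrd, which raises both of these ratios. The interval also crossed the bound of -0.5 in the 37 genes tested in both cultivars (-1.18 to -0.39), though not in the whole list (-1.33 to -0.58). In the whole list non-infested Settler CL lay 0.40 above Byrd. The intervals run over genes, which are not independent, and not over libraries. That explanation and a response of opposite sign in the 2 cultivars cannot be told apart for these genes, and a difference in mite number or timing was not tested. A difference between the infested and non-infested Settler CL plants, raised under other observations for other genes, was not tested for the jasmonate genes either. It would coincide with infestation, so values per group cannot separate it from a response to mites. The raised level, the response of opposite sign, mite number or timing and such a plant difference all stay open.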

How the results depend on the processing

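The mean of at least 1 FPKM and the 2 settings of the test of the difference between responses were planned; the other settings were chosen after the table had been seen. No paired analysis was possible because the table holds 1 value per group. For the same reason leaving out each library, other splits of the libraries, the count-based tools of the plan, its low-count filter and a replicate block were not run. The planned adjusted p of 0.01 for the 4 comparisons, overlaps and lists was replaced by an unadjusted p of 0.01, since the table used here holds none.

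In each of the 4 comparisons the direction with more calls was the same under every setting tried. Counts of genes, of shared genes and of the jasmonate, WRKY, protease inhibitor and photosynthesis calls within 1.5 times of the reported ones are not repeated. With a mean of at least 1 FPKM there were 845 rises and 215 falls in Byrd, 437 rises in Settler CL, 1924 higher and 789 lower genes in Settler CL against Byrd without mites, and 1520 and 2002 with mites; 109 genes rose in both cultivars, 16 WRKY factors rose in Byrd, and 20 list results were enriched in place of 33. With an absolute log2 fold change of at least 2 there were 326 rises and 85 falls in Byrd, 244 and 312 in Settler CL, 1143 higher and 774 lower genes without mites, and 1108 and 1293 with mites. Under the same minimum 30 genes rose in both cultivars, 1 fell in both and 23 rose in Byrd and fell in Settler CL, and 16 list results were enriched. The lists then held 20 jasmonate rises in Byrd and 7 falls in Settler CL, 13 WRKY rises in Byrd and 4 in Settler CL, 13 protease inhibitor rises in Byrd and 2 photosynthesis falls in Settler CL. These filters leave fewer genes by construction.

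The conservative adjustment gave 579 rises and 89 falls in Byrd, 355 and 823 in Settler CL, 1811 higher and 881 lower genes without mites and 1698 higher with mites. It left 57 genes that rose in both, 7 that fell in both and 81 that rose in Byrd and fell in Settler CL, with 18 protease inhibitor rises in Byrd and 14 photosynthesis falls in Settler CL. At an unadjusted p of 0.01 there were 235 falls in Byrd and 22 falls in both cultivars. Without models of suffix LC there were 221 falls in Byrd, 1162 in Settler CL, 1904 higher and 781 lower genes without mites, 1689 higher with mites, 19 falls in both cultivars and 11 photosynthesis falls in Settler CL. Centring gave 19 photosynthesis falls and 40 NLR falls in Settler CL, 22 peroxidases higher in non-infested Settler CL, 5 cell wall growth rises in Settler CL, and 3 falls of the corrected pathogenesis-related list in Settler CL. It also gave 10 glycosyltransferase falls and 5 auxin falls in Settler CL. At an adjusted p of 0.01 the difference between responses held for 362 genes. Centring was not run for that test. Leaving out chromosome 3D, which was not run for that test, moved no count of calls, of shared calls or of the 4 lists named above by over 1.5 times, but in Settler CL ribosomal falls went from 21 to 10, glycosyltransferase falls from 18 to 11 and auxin falls from 8 to 5, and the sugar genes higher in infested Settler CL were no longer enriched (28 of 68, adjusted exact p = 0.0562). Of 123 values of named genes, the conservative adjustment ended 30 calls, p at most 0.01 ended 13 and the larger fold minimum ended 8; the other settings ended none of those they could be run on, and none changed sign.

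The fixed pattern for pathogenesis-related proteins, methionine names included, gave 33 rises of 120 in Byrd (adjusted exact p = 0.0112) and 27 of 133 in Settler CL (adjusted exact p = 0.00112). Set against other calls alone, the share of rises in Byrd was higher for WRKY factors (Fisher's exact p = 0.00274), jasmonate genes (exact p = 0.0017) and protease inhibitors (exact p = 0.00269), but not for phenylpropanoid (exact p = 0.725), cytochrome P450 (exact p = 0.582), cell wall growth (exact p = 0.256), nitrogen (exact p = 0.321) or ethylene genes (exact p = 0.0822). Enriched under every setting were the rises in Byrd of jasmonate genes, WRKY factors, protease inhibitors and the corrected pathogenesis-related list, the jasmonate falls in Settler CL, and the jasmonate and phenylpropanoid genes lower in infested Settler CL; each other list result was ended by at least 1 setting. Of 37 list results, the corrected list included, centring ended 8, the mean of at least 1 FPKM 15, the conservative adjustment 13, the larger fold minimum 24, p at most 0.01 ended 2 and leaving out chromosome 3D ended 1; without the suffix LC 8 ended and 2 could not be run. Depth per library is unknown, which limits what low FPKM values can show.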

Other observations

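The alternatives by chromosome, the tests on segments and the definition of near absent genes were chosen after the clustering on chromosome 3D had been seen; the bounds of the neighbour test were set before its values were computed. The Byrd test on non-infested Settler CL was added after the levels of the 6B genes had been seen, with its bound set before its own value. The minimum of 0.6 FPKM came from looking at the table. The first test for fewer copies of the 3D block took all its tested genes, of which 97.4% lay below 0; it was replaced after that value had been seen by the genes called in Byrd, at first only those tested in Settler CL and then all of them, because most of the block's genes are listed through their fall.

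Subgenomes and chromosomes took unequal shares of the calls. Rises in infested Byrd were more frequent on the D subgenome, with 498 against 436 expected (adjusted exact p = 0.00066, Fisher's exact test), and less so on the B subgenome, with 424 against 515 (adjusted exact p = 2.08e-07). Chromosome 5D held 94 rises of Byrd against 60.3 expected (adjusted exact p = 3.92e-05). These shares depend on what is listed, since every listed gene was called somewhere. Many cultivar calls on a chromosome lower its share of mite calls. Genes higher in non-infested Settler CL numbered 1225 on B against 1146 expected, and 762 on D against 884. The shares of rises therefore do not show that the subgenomes responded differently to mites. Genes lower in non-infested Settler CL than in Byrd were frequent on chromosome 1B, with 156 against 88.5 expected (adjusted exact p = 2.66e-12), and on 7A, with 117 against 70.2 (adjusted exact p = 5.99e-08). Genes higher in Settler CL were frequent on 6B, with 251 against 193 expected (adjusted exact p = 3.72e-06) without mites and 229 against 163 (adjusted exact p = 3.3e-08) with them.

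Smaller groups not described above moved in part. Auxin genes rose in 17 and fell in 2 of the 69 listed members in Byrd, and rose in 3 and fell in 8 in Settler CL. Histones rose in 10 of 49 listed genes in Byrd with no fall. Expansins rose in 10 of 27 in Byrd, while 4 fell in Settler CL and none rose. The auxin list was not enriched among the rises of Byrd (adjusted exact p = 0.148) or the falls of Settler CL (adjusted exact p = 0.64); the histone and expansin counts were not tested.

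The distal block of chromosome 3D stood lower in infested Settler CL than in the other 3 groups. Plants or RNA of Byrd among the infested samples would place it between the cultivars, but its median log2 ratio to non-infested Byrd was -1.38 (quartiles -1.67 and -1.06), and -1.32 in the 22 block genes called in Byrd (95% interval over genes -1.89 to -0.63), and a mite response common to both cultivars is argued against by the 0.409% of its tested genes that fell in Byrd. Because most of the block's genes are listed through their fall, those 22 genes, called in a comparison with no Settler CL library, were used for the next test: 90.9% of them lay below 0 in Settler CL (median -1.26, against -0.01 for 1690 such genes on other chromosomes), among them all 13 that were tested there. A candidate explanation, stated as a hypothesis, is fewer copies of the distal part of 3D in some or all infested Settler CL plants. A repression of the region in Settler CL by mite feeding, which would look alike in these values, stays open and was not tested.

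A second set of genes was near absent or near exclusive in infested Settler CL, by at least 10 times to the nearest other group and with at least 0.6 FPKM in the higher. It held 60 near absent genes, 25 of them on chromosome 6B, and 73 near exclusive genes, 11 on 4A and 10 on 3D, while each other group held 23 to 33 near absent genes and 11 to 42 near exclusive ones. With at least 1 FPKM the counts were 36 and 53. Neighbouring genes of unlike description shared the pattern in 14 pairs, against a highest value of 6 in 10000 shuffles (8 pairs against 4 with at least 1 FPKM), and in 3 pairs for non-infested Settler CL, which also passed the 99% bound, against 0 and 1 in the Byrd groups. Segments that differ between the infested and non-infested Settler CL plants would give such pairs. Unlike means only that the description texts differ. Some neighbours are consecutive models of suffix LC, such as TraesCS6B03G1040000LC and TraesCS6B03G1040100LC. Whether such models are parts of 1 transcript was not tested, and the shuffles treat them as separate genes. The 6B genes stood in non-infested Settler CL at a median of 0.537 of their Byrd level; RNA of Byrd in that group would bring all Byrd genes, yet 79.2% of 192 genes at 0 in infested Settler CL lay over 10 times below Byrd there, so a cultivar made up of unlike plants may be a candidate explanation that values per library would test.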
